A study of Homo sapiens with 6 samples.

How the data were processed

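Biotin-labelled cRNA from total RNA of scalp biopsies was measured on Affymetrix arrays of 54675 probe sets, per the labels. The deposited values are MAS5 signal intensities on a linear scale in arbitrary units, 1 per probe set and array, and MAS5 is named per the submitters' processing notes. MAS5 summarises the probe pairs of a probe set and scales each array by its trimmed mean. The mean without the lowest and highest 2% of probe sets was about 500 on each of the 6 arrays, as computed here. The medians and lower quartiles differed between arrays, so the deposited values had not been quantile normalized, and dim probe sets lay higher on arrays with weaker signal. The scaling target, the software version and the handling of the pooled array are not given in the sources used here. The pool's spike-in signals lay below those of all FFA arrays. The hybridization spike-ins rose in the same order as the median signal over the 6 arrays, so they do not show a separate hybridization. The poly-A spike-ins did not follow that order. The pool may have been prepared or hybridized apart from the FFA arrays, which would bear on every difference from the pool. A further deposited table held the same signals for the 5 FFA arrays (all 54675 probe sets were identical), with the detection call of each probe set (present, marginal or absent) and the authors' MAS5 change p-value of each FFA array against the pool. A change p-value compares 1 array with 1 array, near 0 where the FFA array is higher and near 1 where it is lower, and says nothing of the spread between samples. Detection calls were used for the 5 FFA arrays only.

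Groups were taken from the sample titles, as 3 affected arrays, 2 unaffected arrays and 1 pool of 10 healthy people. No label states that a number marks a patient, so the comparison of affected with unaffected scalp was not paired, and a fit with the replicate number as a block was run as an alternative. Groups, tests, filter, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

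Signals were transformed as log2(signal + 16). Of the probe sets, 62 were controls, 41091 named 1 gene, 1801 named several genes and 11721 named none, and the gene identifier was found in the human RefSeq gene table for 41037 of those naming 1 gene, which named 19775 genes. No genome positions were used. Probe sets called Present on at least 2 of the 5 FFA arrays were kept (26861, of which 21139 named 1 gene and were kept), and each gene was represented by its probe set with the highest mean, which left 12339 genes. Genes on the Y chromosome, the genes of X inactivation, and genes whose signal follows a common deletion or HLA haplotype were left out because the samples come from patients. Probe sets naming several genes or none were not tested gene by gene. Probe sets of the _x_at kind can bind related transcripts, and among the named genes they read IFNA7, BASP1-AS1, IGLC1, GUSBP11, CYP1A2, CXCL8, MGST1, TPSAB1 and FN1. Where named genes had other Present probe sets, their direction was compared with that of the chosen one. In affected against unaffected scalp 22 of 49 named genes had another, and 4 had one that pointed the other way. Against the pool this held for 7 of 21 in affected and 3 of 8 in unaffected scalp. The difference of another probe set was under 50% of the chosen one's, or opposite, for 8, 11 and 6 genes in the 3 comparisons.

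All 6 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with a mean per group and 3 residual degrees of freedom, moderated with a trend in the mean (eBayes, prior degrees of freedom 7.46), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold in each comparison. The pool's spread was assumed to equal that of the FFA groups. 41 gene lists for skin, hair follicle, immune, mitochondrial and protein turnover genes were tested with limma camera at a preset correlation of 0.01 between members, over the 39 lists with at least 5 measured members, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the arrays. With an estimated correlation limma camera tests on the residual degrees of freedom of the fit, 3 here, so it had little power. In affected against unaffected scalp it gave adjusted p = 0.722 both for the respiratory chain (estimated correlation 0.88) and for interferon-stimulated genes (0.09). Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. A gene called Present on none of a group's arrays was taken as not above background there, and its fold change is given as a bound on log2(signal + 16), with the higher of its own signal and the lowest signal called Present on that array (31.6 and 29.1 on the unaffected arrays, 24.7, 71.3 and 36.7 on the affected arrays). The pool has no calls, so a signal under 24.7 was treated in this way and set to 24.7. Bounds compare means of log2 values, are rounded down, and cover the background and not the spread between samples. Where a dim group's own signals lay above these floors, as for FADS2, OAS1 and GZMK, the bound equals the fitted fold change. Arrays not called Present in the brighter group entered with their signals, and 24.7 is no measured background of the pool. Such bounds are not strict lower limits.

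The text names genes by a rule. Of the genes past the threshold whose arrays did not overlap between groups, the 10 with the largest rise and the 10 with the largest fall are named. Where fewer than 10 passed in a direction, the names are filled to 5 by the largest moderated statistic and given as not past the threshold. Up to 4 members per list with the largest moderated statistic are named, and always PPARG, PPARGC1A, KRT15, CYP1B1, IFNG, CXCL9, CXCL10, COL1A1 and FN1. Uncharacterised transcripts are not named.

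The fit was tested on simulated data of 12339 genes with the spread of these arrays, in 10 simulations with 200 changed genes. For affected against unaffected scalp it recovered 14.9%, 84.0% and 94.2% of genes changed by 1, 2 and 4 on the log2 scale, with 7.95% false calls. For affected scalp against the pool it recovered 4.03%, 58.4% and 89.8%, with 7.33% false calls, and for unaffected scalp against the pool 2.84%, 59.9% and 92.7%, with 7.69% false calls. Simulated lists of 25 members shifted by 0.5 were called in 100%, 100% and 97.5% of cases in these comparisons, and lists with no shift in 0.278%, 0% and 0.278%. The simulated genes were independent, so these shares say nothing about lists whose members move together.

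Alternatives were quantile normalization between arrays, centring each array on its median, no filter (19720 genes), a stricter filter (Present on all arrays of at least 1 FFA group, 11003 genes), pseudocounts of 1 and 64, no trend in the moderation, the mean of a gene's probe sets, all 26760 probe sets one by one, only the groups compared, the replicate block, the estimated correlation, the deposited change p-values, and leaving out each of the 5 FFA arrays. The probe sets with an above-median mean over all 6 arrays (12873 genes) and the log2 actin 3' to 5' ratio as a covariate were added after the data were seen. The median log2 difference of all genes was -0.05, -0.03 and 0.04 in the 3 comparisons, and quantile normalization or median centring moved it by less than 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.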

Results

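Frontal fibrosing alopecia (FFA) is a scarring hair loss in which the frontal hairline recedes as hair follicles are replaced by scar. Gene expression was measured by Affymetrix microarray in total RNA from scalp biopsies, and 6 arrays were analysed. 3 arrays held affected frontal scalp of people with FFA, 2 arrays held unaffected occipital scalp of people with FFA, and 1 array held RNA pooled from the occipital scalp of 10 healthy people. The study's stated purpose was to explore expression in FFA, and its title names faults of mitochondria and of protein breakdown by the ubiquitin-proteasome system, along with oxidative stress. Affected scalp was frontal on every array and the other scalp was occipital on every array, so region and disease state were not separated. Nothing beyond the labels says that the arrays of a group came from separate donors, and affected and unaffected arrays may come from the same patients. P-values of single genes therefore measure the spread between these samples, whose number limits the precision. List p-values of limma camera at the preset correlation set members against the other genes. They do not measure how far a list's mean varies between samples.

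The arrays differed in signal quality. The median signal was 117.1 on the pool, 195.1 and 170.3 on the unaffected arrays, and 237.4, 323.5 and 214.9 on affected arrays 1, 2 and 3, at the same trimmed mean on every array. Probe sets called Present made up 44.8% and 46.5% of the unaffected arrays and 45.3%, 35.9% and 41.8% of the affected arrays, and no calls of this kind were used for the pool. The ratio of the 3' to the 5' actin probe set, which rises as RNA is shortened, was 2.15 on the pool, 7.88 and 6.87 on the unaffected arrays, and 12.6, 14.8 and 7.67 on affected arrays 1, 2 and 3. The same ratio for GAPDH was 1.27 on the pool, 1.84 and 1.66 on the unaffected arrays, and 1.76, 1.54 and 1.53 on affected arrays 1, 2 and 3, so the 2 ratios agreed on the pool and not between the FFA groups. Affected replicate 2 had the fewest Present calls and the highest actin ratio. Spike-in controls averaged 2874 for hybridization and 1947 for poly-A RNA on the pool, against 5292 to 16361 and 18302 to 90868 on the FFA arrays. In the values below, ± after a log2 difference is the SE of the limma fit and ± after a signal is the SD over 2 unaffected or 3 affected arrays.

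Affected scalp was first compared with unaffected scalp, which addresses what differs between a lesion and skin of the same disease outside it. Genes of the sebaceous gland and of lipid synthesis were lower in affected scalp as a group, as were genes of the follicle epithelium and hair shaft, the respiratory chain and the proteasome (each with adjusted p = 0.722 with an estimated correlation). The respiratory chain and proteasome calls ended without affected replicate 2, and both lists passed as higher with the actin ratio as a covariate. Interferon-stimulated genes and markers of T cells and macrophages were higher as groups (likewise adjusted p = 0.722 with an estimated correlation). Of 39 gene lists tested with limma camera, 19 passed the threshold, 6 of them higher and 13 lower in affected scalp, and 0 passed with the correlation between members estimated from these arrays (smallest adjusted p = 0.722). Gene by gene, 0 of 12339 genes passed in limma (smallest adjusted p = 0.563). At an unadjusted p under 0.05 there were 1089 genes, 592 higher and 497 lower, where chance gives 617. The arrays of the groups did not overlap for 3797 genes, or 30.8%, where chance gives 20%.

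The sebaceous gland and lipid synthesis list showed the largest shift between affected and unaffected scalp. 30 of its 32 measured members were lower in affected scalp, with a median log2 difference of -1.35 (limma camera, adjusted p = 7.29e-16; adjusted p = 0.722 with an estimated correlation). Adjusted over the list alone, 19 members fell and 13 did not pass, against 0 over all genes. FABP7, a fatty acid binding protein, had a signal of 5287 ± 2014 in unaffected (SD, n = 2) and 1178 ± 652 in affected scalp (SD, n = 3), a log2 difference of -2.24 ± 0.44, while 1 of its 2 other Present probe sets gave 1.41. SOAT1, which esterifies cholesterol, differed by -2.36 ± 0.55, with its 2 other Present probe sets at -1.36 and -0.97. The sebaceous keratin KRT79 differed by -1.76 ± 0.41. FADS2, the desaturase that makes sapienic acid in human sebum, was called Present on both unaffected arrays and on 0 affected arrays. Its affected signals lay above the lowest Present signals, so its bound of 3.50-fold equals the fitted fall (log2 difference -1.81 ± 0.37). ABHD5, a co-activator of triglyceride breakdown, differed by -1.50 ± 0.30 without passing over all genes (adjusted p = 0.563). The list means did not overlap between groups, lying from -1.38 to -0.29 on affected and at 0.05 and 0.98 on unaffected arrays. Without unaffected replicate 2 the difference in the list mean was -0.79, against -1.26 with all arrays, and with the actin ratio as a covariate it was -0.58.

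Cholesterol synthesis genes fell as a list (18 measured, median log2 difference -0.65, adjusted p = 0.00115), and so did fatty acid beta-oxidation genes (18 measured, median -0.47, adjusted p = 0.00228). Both had adjusted p = 0.722 with an estimated correlation, and 0 members of either passed over all genes or adjusted over the list alone. The sterol regulator INSIG1 differed by -1.47 ± 0.44, the demethylating enzyme MSMO1 by -1.51 ± 0.56 and the beta-oxidation dehydrogenase HADH by -1.50 ± 0.46. The 2 other Present probe sets of HADH gave -1.05 and -0.37. INSIG1 was -0.90 without unaffected replicate 2, and MSMO1 -0.92 and HADH -0.96 without affected replicate 2. Without unaffected replicate 2 both calls ended (list means -0.33 and -0.21, adjusted p = 0.0675 and 0.311). Without affected replicate 2 the list means were -0.36 and -0.24, against -0.58 and -0.47 with all arrays, and both calls held. The beta-oxidation mean was -0.72 without unaffected replicate 1. Without a filter it was -0.31, and its call held. The cholesterol mean was -0.06 and the beta-oxidation mean 0.088 with the actin ratio as a covariate, and neither passed.

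**Figure D1:**
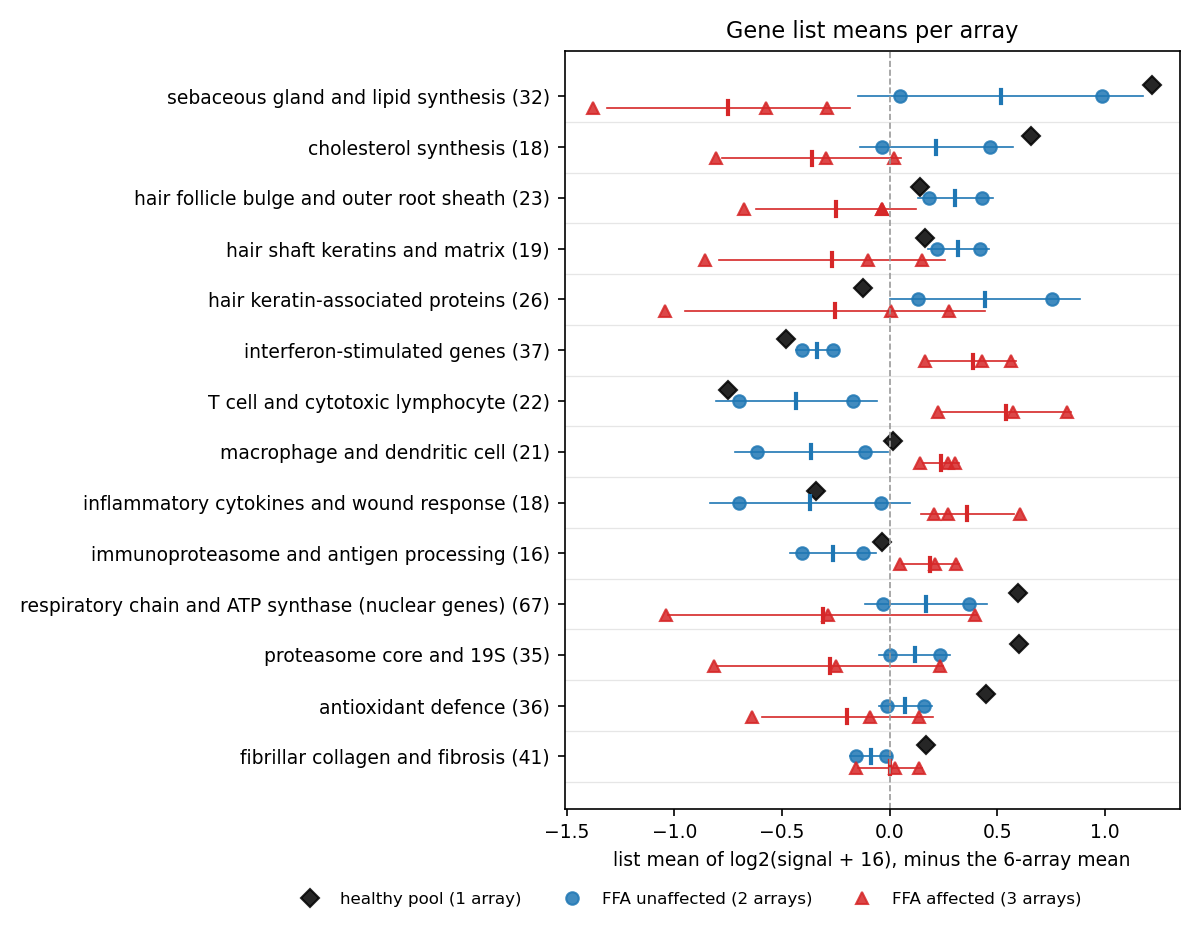
Mean of log2(signal + 16) over the measured members of 14 gene lists on each array, relative to the mean of the 6 arrays (x axis, log2 units), with the number of measured members in brackets. Points are arrays, short vertical bars are group means and thin lines are ± 1 SD of the 3 affected or 2 unaffected arrays. The affected arrays lay between -1.38 and -0.29 for the sebaceous list and between 0.16 and 0.56 for interferon-stimulated genes, apart from both unaffected arrays, while the respiratory chain and proteasome means overlapped between these groups.

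4 of 5 lists of hair follicle genes were lower in affected scalp. The dermal papilla list did not pass and went the other way (9 of 12 measured members higher, median log2 difference 0.29, adjusted p = 0.165). The bulge and outer root sheath list, which holds markers of the follicle stem cell region, had 21 of 23 measured members lower (median log2 difference -0.64, adjusted p = 4.88e-05; adjusted p = 0.722 with an estimated correlation). Adjusted over the list alone, 1 member fell, TGFB2, a growth factor that drives follicle regression (-1.35 ± 0.29), against 0 over all genes, and 1 of 2 other Present probe sets of TGFB2 gave 0.10. SOX9, a transcription factor of follicle stem cells, had a signal of 15249 ± 2757 in unaffected (SD, n = 2) and 7238 ± 1473 in affected scalp (SD, n = 3). LHX2, another stem cell regulator, differed by -1.04 ± 0.34 and the bulge keratin KRT15 by -1.05 ± 0.47, and SOX9, LHX2 and KRT15 did not pass. KRT15 was -0.58 without affected replicate 2. CYP1B1, an enzyme of estrogen metabolism, differed by -0.90 ± 0.32 (adjusted p = 0.563). Hair shaft keratins and matrix genes (19 measured, median -0.65, adjusted p = 0.000489), keratin-associated proteins (26 measured, median -0.74, adjusted p = 8.35e-05) and inner root sheath genes (14 measured, median -0.42, adjusted p = 0.0219) were lower as lists, each with adjusted p = 0.722 with an estimated correlation and 0 members past over all genes or adjusted over the list alone. The desmosomal cadherin DSG4 differed by -1.17 ± 0.32 and KRTAP17-1 by -1.27 ± 0.42.

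The follicle lists leaned on single arrays. Without affected replicate 2 the list means were -0.34 for bulge and outer root sheath, -0.29 for hair shaft and -0.30 for keratin-associated proteins, against -0.55, -0.59 and -0.70 with all arrays, and these calls held. Without unaffected replicate 1 the keratin-associated protein call ended (list mean -0.38, adjusted p = 0.0758). The inner root sheath call ended without unaffected replicate 1 (-0.28, adjusted p = 0.271), without affected replicate 1 (-0.41, adjusted p = 0.0623) and without affected replicate 2 (-0.21, adjusted p = 0.066). Adjusting for the actin ratio gave a bulge mean of -0.28 and a keratin-associated protein mean of -0.32, both past the threshold. The hair shaft mean was then -0.08 and the inner root sheath mean 0.017, and neither passed, while the dermal papilla mean was 0.55 and passed as higher (adjusted p = 0.0266).

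Interferon-stimulated genes rose as a list in affected scalp. 36 of 37 measured members were higher, with a median log2 difference of 0.72 (limma camera, adjusted p = 3.85e-12; adjusted p = 0.722 with an estimated correlation). Adjusted over the list alone, 6 members rose and 31 did not pass, against 0 over all genes. CXCL10, a chemokine that draws T cells, had a signal of 309 ± 111 in unaffected (SD, n = 2) and 1506 ± 839 in affected scalp (SD, n = 3), a log2 difference of 2.05 ± 0.52. EPSTI1 differed by 1.39 ± 0.33 and MX2, an antiviral GTPase, by 1.01 ± 0.27. OAS1, an antiviral synthetase, was called Present on 2 affected and 0 unaffected arrays, with a fitted rise of 2.17-fold (log2 difference 1.12 ± 0.32). T cell and cytotoxic lymphocyte markers were higher for all 22 measured members of 48 listed (median 0.88, limma camera, adjusted p = 1.11e-10; adjusted p = 0.722 with an estimated correlation). Over all genes or adjusted over the list alone, 0 members passed. The filter needs Present calls on 2 of 5 FFA arrays, 3 of them affected, so affected arrays alone can admit a gene. It may set part of this share and of the interferon share. In the T cell list 4 members, and in the interferon list 5, were Present on no array of 1 group. The chemokine CCL5 differed by 1.64 ± 0.42, the interleukin receptor chain IL2RB by 1.09 ± 0.33 and the T cell adhesion molecule CD2 by 1.02 ± 0.35. GZMK, a granzyme of cytotoxic cells, was called Present on 2 affected and 0 unaffected arrays. Its fitted rise between means on the log2 scale was 3.38-fold, with 1.69-fold without unaffected replicate 1 and 6.78-fold without unaffected replicate 2. Without unaffected replicate 1 the log2 differences were 0.92 for CCL5 and 0.47 for CD2 (1.57 without replicate 2). The interferon-induced chemokine CXCL9 differed by 1.95 ± 0.62 and IFNG itself by 0.97 ± 0.56, with adjusted p = 0.563 and 0.584, and without affected replicate 1 CXCL9 differed by 1.25. Both list calls held without each of the 5 FFA arrays and with the actin ratio as a covariate.

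Macrophage and dendritic cell markers were higher too (20 of 21 measured members, median 0.55, adjusted p = 1.41e-06), as were inflammatory cytokine and wound response genes (16 of 18, median 0.84, adjusted p = 0.000104), immunoproteasome and antigen processing genes (14 of 16, median 0.52, adjusted p = 0.000481) and mast cell markers (9 of 11, median 0.42, adjusted p = 0.0353). Each had adjusted p = 0.722 with an estimated correlation. The filter may set part of these shares too, and 2 macrophage and dendritic cell members were Present on no array of 1 group. Over all genes 0 members passed. Adjusted over the list alone, 1 inflammatory gene rose, the lymphocyte-attracting chemokine CCL19 (1.43 ± 0.33), and 1 antigen processing gene rose, the MHC class I transactivator NLRC5 (1.34 ± 0.35). Of members that did not pass, LYZ differed by 1.31 ± 0.42, the collagenase MMP1 by 1.52 ± 0.51 and the peptide transporter TAP1 by 0.98 ± 0.31, and the monocyte receptor gene CD14 had a signal of 379 ± 154 in unaffected (SD, n = 2) and 765 ± 225 in affected scalp (SD, n = 3). Without unaffected replicate 1 LYZ differed by 0.55 (2.06 without replicate 2) and CD14 by 0.59, over 1.5 times less than with all arrays. Without unaffected replicate 1 the macrophage mean was 0.35, against 0.60 with all arrays, and its call held. Without the same array the inflammatory (0.40, adjusted p = 0.0677), antigen processing (0.31, adjusted p = 0.0766) and mast cell calls (0.32, adjusted p = 0.112) ended. The mast cell call also ended without affected replicate 3 (0.22, adjusted p = 0.229). The replicate block, in which affected replicate 3 has no partner, gave the same difference (0.22, adjusted p = 0.242). The mast cell mean was 0.66 with the actin ratio as a covariate.

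**Figure D2:**
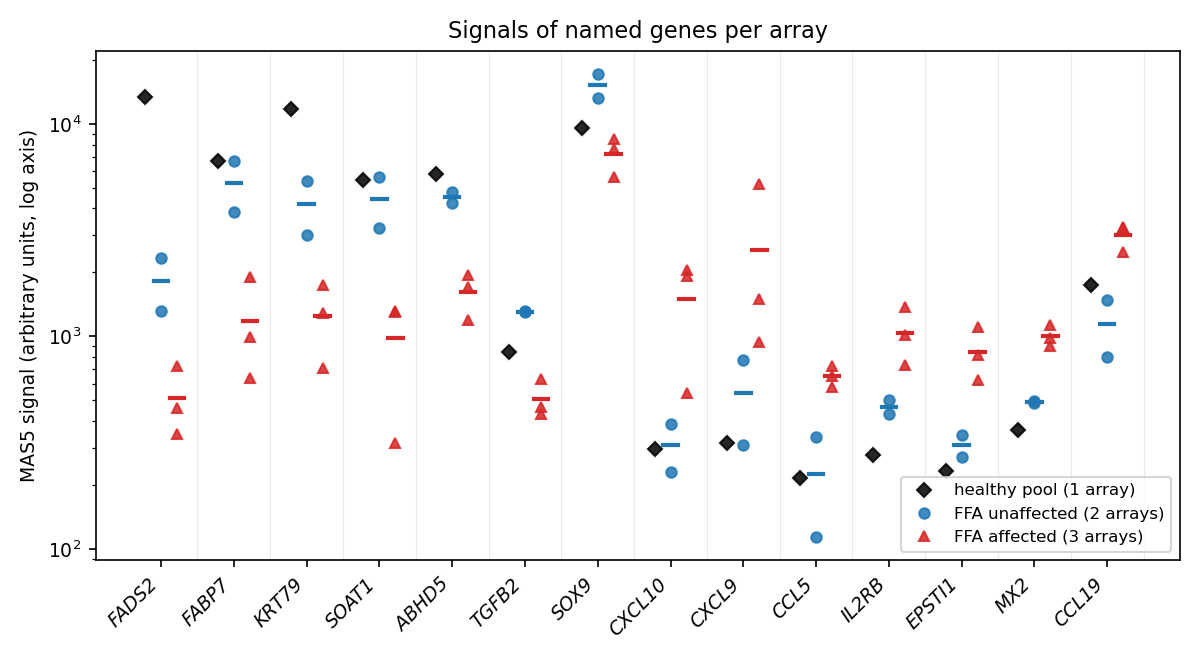
MAS5 signal (y axis, log scale, arbitrary units) of 14 genes on each of the 6 arrays, with horizontal bars at the means of the 2 unaffected and 3 affected arrays. FADS2 read 13381.8 on the healthy pool and between 348.8 and 728.0 on the affected arrays, while CXCL10 read between 539.1 and 2046.2 on the affected arrays and at most 386.8 on the others.

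Among the processes named in the study's title, the respiratory chain and ATP synthase list was lower in affected scalp (64 of 67 measured members, median log2 difference -0.48, adjusted p = 2.45e-06; adjusted p = 0.722 with an estimated correlation). The mitochondrial ribosome and import list (65 of 75, median -0.31, adjusted p = 0.00115), the proteasome core and 19S list (34 of 35, median -0.41, adjusted p = 0.000299) and the ubiquitin activation and conjugation list (19 of 23, median -0.38, adjusted p = 0.0101) were also lower, each with adjusted p = 0.722 with an estimated correlation. Antioxidant defence (30 of 36, median -0.29, adjusted p = 0.0127) and heat shock and unfolded protein response genes (19 of 21, median -0.30, adjusted p = 0.0353) were lower as lists. Both of these had adjusted p = 0.722 with an estimated correlation, and 0 members of the 6 lists passed over all genes or adjusted over the list alone. The complex I subunit NDUFS1 differed by -0.66 ± 0.32, with 1 of 2 other probe sets at -0.03, the complex III subunit UQCRQ by -1.15 ± 0.59 and the 19S subunit PSMD11 by -0.77 ± 0.34. UQCRQ and PSMD11 were both -0.48 without affected replicate 2, UQCRQ was -1.76 without affected replicate 3, and NDUFS1 was -0.99 and -0.33 without unaffected replicates 1 and 2. The mitochondrial ribosomal gene MRPL19 differed by -1.17 ± 0.32 on the probe set used, while its 2 other Present probe sets gave 0.03 and 0.27. MGST1, a glutathione transferase, differed by -1.27 ± 0.47, with 1 of 3 other probe sets at -0.03, and GCLM, which supports glutathione synthesis, by -0.87 ± 0.33. MGST1 was -0.70 without unaffected replicate 2 and GCLM -0.58 without affected replicate 2. PPARG, a regulator of lipid metabolism, differed by -0.57 ± 0.41 and PPARGC1A, a co-activator of mitochondrial biogenesis, by 0.04 ± 0.38 (-0.36 after quantile normalization), with adjusted p = 0.615 and 0.963. Leaving out 1 array gave -1.17 to 0.021 for PPARG and -0.26 to 0.24 for PPARGC1A.

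These differences followed affected replicate 2, the array with the fewest Present calls. The respiratory chain mean was -1.04 on that array and -0.29 and 0.39 on the other affected arrays, against -0.03 and 0.37 on the unaffected arrays. Without affected replicate 2 the calls ended for the respiratory chain (list mean -0.12, adjusted p = 0.066), the mitochondrial ribosome (-0.06, adjusted p = 0.228), the proteasome (-0.12, adjusted p = 0.074), antioxidant defence (-0.05, adjusted p = 0.274) and heat shock (-0.10, adjusted p = 0.249). The ubiquitin conjugation mean was then -0.16, against -0.29, and still passed. Without unaffected replicate 2 the antioxidant (-0.18, adjusted p = 0.162) and heat shock (-0.14, adjusted p = 0.411) calls ended and the respiratory chain mean was -0.28. Without affected replicate 3 the respiratory chain (-0.83), mitochondrial ribosome (-0.51), proteasome (-0.65) and antioxidant (-0.44) means were larger, and without unaffected replicate 1 the heat shock mean was -0.43. After quantile normalization the proteasome (-0.21, adjusted p = 0.172), ubiquitin (-0.13, adjusted p = 0.284), antioxidant (-0.19, adjusted p = 0.208) and heat shock (-0.07, adjusted p = 0.886) calls ended, and the respiratory chain mean was -0.27 (adjusted p = 0.0151). The respiratory chain (0.39), mitochondrial ribosome (0.25) and proteasome (0.23) means turned positive and passed as higher with the actin ratio as a covariate. The antioxidant (0.16) and heat shock (0.068) means turned positive without passing, and the ubiquitin mean (-0.03) no longer passed.

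The fibrillar collagen and fibrosis list did not pass (41 measured members, median log2 difference 0.09, adjusted p = 0.25). Its mean was 0.087 with all arrays and ranged from 0.018 to 0.167 without 1 array. Adjusted over the list alone, TGFB1, the main profibrotic growth factor, rose (1.32 ± 0.32) and TGFB2 and the matrix glycoprotein THBS1 (-1.14 ± 0.30) fell, against 0 members over all genes. Another Present probe set of THBS1 gave 0.87. The fibronectin gene FN1 differed by 0.88 ± 0.31 and the collagen gene COL1A1 by 0.79 ± 0.44, and neither passed. The list passed as higher after quantile normalization (list mean 0.25, adjusted p = 1.68e-06) and with the actin ratio as a covariate (0.23, adjusted p = 0.0133). The other genes with the largest moderated statistics also did not pass over all genes. The S100 family gene S100A7A differed by 1.86 ± 0.36, the adhesion receptor ADGRE5 by 1.71 ± 0.36, the secreted phospholipase PLA2G2A by 1.40 ± 0.30, the BMP antagonist GREM1 by 1.41 ± 0.31 and the itch-related cytokine receptor IL31RA by -1.30 ± 0.30. TMEM156 was called Present on 2 affected and 0 unaffected arrays, with a bound of 6.45-fold (5.57-fold without affected replicate 2).

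With the replicate number taken as a block over the 5 FFA arrays, which leaves 1 residual degree of freedom, limma called 484 genes (200 higher) between affected and unaffected scalp against 0 without it, and 24 lists against 19. Affected replicate 3 shares its number with no unaffected array, so the block takes it up. The differences equal those without that array, as for the respiratory chain list mean (-0.83 in both). No label says that a number marks a patient, and the correlation across genes of replicate 1 minus replicate 2 in affected and in unaffected scalp was -0.05. Affected replicate 2, which enters this value, had the lowest correlations with the other arrays (0.740 to 0.874). The value therefore speaks neither for nor against pairing.

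Affected scalp was next compared with the healthy pool, which addresses what differs between lesions and scalp without the disease. Limma called 186 of 12339 genes, 167 higher and 19 lower in affected scalp (smallest adjusted p = 0.0125). Sebaceous and lipid synthesis genes, mitochondrial and proteasome genes were lower as lists, and T cell and interferon-stimulated genes were higher. 17 of 39 lists passed in limma camera, 4 higher and 13 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.817). At an unadjusted p under 0.05 there were 2701 genes, 1725 higher and 976 lower. The arrays did not overlap for 8372 genes, or 67.8%, where chance gives 50%. The spread of the pool could not be estimated from 1 array and was assumed to equal that of the FFA groups.

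The largest fall against the pool was that of FADS2, with a signal of 13382 in the pool and 513 ± 195 in affected scalp (SD, n = 3). FADS2 was called Present on 0 of the 3 affected arrays. Its bound of 26.4-fold equals the fitted fall between means on the log2 scale (-4.73 ± 0.47, limma, adjusted p = 0.0125). The sebaceous keratin KRT79 fell (log2 difference -3.31 ± 0.51), as did FABP7 (-2.64 ± 0.55), the neuropeptide gene GAL (-3.08 ± 0.61) and the mitochondrial permeability regulator PPIF (-2.27 ± 0.37). The other Present probe set of GAL gave 0.83 and 1 of 2 other probe sets of FABP7 gave 2.72, both in the other direction. The immunoglobulin light chain gene IGLC1 (-3.35 ± 0.45), the hair gene KRTAP19-3 (-2.90 ± 0.46), the glycine cleavage enzyme GLDC (-2.86 ± 0.47), the lipase inhibitor ANGPTL4 (-2.50 ± 0.49) and PLN, a calcium pump regulator of muscle (-2.29 ± 0.48), fell as well.

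The genes with the largest rises were dim on the pool array. The erythroid heme enzyme ALAS2 rose with a bound of 8.50-fold, the interferon gene IFNA7 with 8.43-fold, ADAM21 with 7.03-fold and TMEM221 with 6.79-fold. Without 1 affected array these bounds ranged from 5.75-fold (TMEM221) to 10.6-fold (ALAS2). The non-coding or pseudogene transcripts PRDX6-AS1, LINC00930, SMCR5, BASP1-AS1 and POM121L8P rose with bounds of 12.3-, 11.9-, 8.30-, 7.90- and 7.74-fold. Without 1 affected array these bounds ranged from 5.56-fold (BASP1-AS1) to 15-fold (PRDX6-AS1). ST3GAL3, a sialyltransferase, rose by 3.91 ± 0.56 on the log2 scale. IFNA7, ADAM21, TMEM221 and ST3GAL3 were each called Present on 1 of 3 affected arrays. The 167 higher genes had a median pool signal of 74.6, against 806.9 over all genes and 4584 for the 19 lower genes. All 167 higher and all 19 lower genes lay on the same side of the pool in unaffected scalp, with median log2 differences of 1.85 and -1.46 there against 2.69 and -2.27 in affected scalp. The shared pool array gives such agreement by itself, since in 100 simulations of groups that do not differ 99.3% and 100% of genes chosen in the same way lay on the same side.

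The count of genes called against the pool changed with the array set and the scaling. It was 302 without affected replicate 2 and 825 without affected replicate 3, and limma called 0 genes without affected replicate 1 (2284 at an unadjusted p under 0.05), after quantile normalization (1317) and with the actin ratio as a covariate (964). In the authors' deposited table of change p-values, 134 genes were higher and 518 lower than the pool on all 3 affected arrays (p under 0.001 or over 0.999), a balance opposite to that of the limma calls.

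Sebaceous and lipid synthesis genes fell as a list against the pool (30 of 32 measured members, median log2 difference -2.10, adjusted p = 5.87e-14; adjusted p = 0.817 with an estimated correlation). Over all genes 4 members fell, and adjusted over the list alone 24 did. Cholesterol synthesis genes had a median of -1.34 (18 measured, adjusted p = 0.00016; adjusted p = 0.817 with an estimated correlation), with 0 members past over all genes and, adjusted over the list alone, 13 lower and 2 higher. DHCR7, which makes cholesterol in the last step, differed by -2.12 ± 0.50 and HMGCS1 by -2.15 ± 0.63. Beta-oxidation genes were all lower (18 of 18, median -0.92, adjusted p = 1.06e-05; adjusted p = 0.817 with an estimated correlation), with 0 members past over all genes and 4 adjusted over the list alone. HADHA differed by -1.49 ± 0.36, with its 2 other Present probe sets at -0.94 and -0.47. HADH differed by -2.21 ± 0.58, with 1 other Present probe set at 0.06. Peroxisome biogenesis genes had a median of -0.46 (15 measured, adjusted p = 0.0274; adjusted p = 0.817 with an estimated correlation), with 0 members past over all genes and 1 adjusted over the list alone. The actin ratio was lower on the pool than on every FFA array. With it as a covariate the list means turned positive for sebaceous (0.71), cholesterol (0.99), beta-oxidation (1.14) and peroxisome genes (0.66), and none passed. The peroxisome call also ended after quantile normalization (-0.58, adjusted p = 0.0551) and with the stricter filter (-0.58, adjusted p = 0.0566).

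Respiratory chain and ATP synthase genes were lower than in the pool for all 67 measured members (median log2 difference -0.86, adjusted p = 8.25e-10; adjusted p = 0.817 with an estimated correlation). The proteasome core and 19S list (34 of 35, median -0.91, adjusted p = 1.3e-07), the mitochondrial ribosome and import list (66 of 75, median -0.74, adjusted p = 1.78e-07), antioxidant defence (33 of 36, median -0.76, adjusted p = 5.23e-05), ubiquitin conjugation (20 of 23, median -0.60, adjusted p = 0.0117) and heat shock genes (18 of 21, median -0.50, adjusted p = 0.0198) were lower too. These 5 lists also had adjusted p = 0.817 with an estimated correlation. Over all genes 0 members of these lists passed. Adjusted over the list alone, 3 proteasome genes fell, PSMD3 (-2.03 ± 0.49), PSMC3 (-1.59 ± 0.40) and PSMB5 (-1.71 ± 0.46), and in the mitochondrial ribosome list MRPL19 fell (-1.87 ± 0.41) and the import chaperone TIMM8A rose (3.12 ± 0.67). The 2 other Present probe sets of MRPL19 gave 0.20 and 0.21, and the other of TIMM8A gave 0.02. The cytochrome gene CYC1 differed by -1.97 ± 0.49, NDUFS1 by -1.33 ± 0.41 with 1 other probe set at 0.13, GCLM by -1.57 ± 0.42 and the heme oxygenase HMOX1 by -1.12 ± 0.38. PPARG differed by -1.06 ± 0.51 and PPARGC1A by -0.39 ± 0.48 (-0.19 and -0.69 without affected replicates 1 and 3), and neither passed.

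Without affected replicate 2 the list means against the pool were smaller and still past the threshold for the respiratory chain (-0.54 against -0.91), the mitochondrial ribosome (-0.41 against -0.63), antioxidant defence (-0.43 against -0.65) and heat shock (-0.21 against -0.40). The antioxidant mean was -0.42 with the mean of the probe sets and still passed. After quantile normalization the respiratory chain (-0.56) and proteasome (-0.51) means still passed, and the ubiquitin (-0.15, adjusted p = 0.431) and heat shock (-0.10, adjusted p = 0.386) calls ended, the latter also with the stricter filter (-0.40, adjusted p = 0.0519). With the actin ratio as a covariate the means turned positive and passed as higher for the respiratory chain (2.46), proteasome (1.54), mitochondrial ribosome (1.43) and antioxidant lists (1.04), and turned positive without passing for heat shock (0.98) and ubiquitin conjugation (0.57).

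T cell and cytotoxic lymphocyte markers rose as a list against the pool (22 of 22 measured members, median log2 difference 1.30, adjusted p = 2.16e-06; adjusted p = 0.817 with an estimated correlation). The filter on calls of the FFA arrays may set part of this share and of the interferon share below. The perforin gene PRF1 rose over all genes (2.13 ± 0.42, adjusted p = 0.0413), while its other Present probe set gave 0.17, and adjusted over the list alone PRF1 and IL2RB (1.80 ± 0.41) rose. Interferon-stimulated genes were higher for 34 of 37 members (median 0.76, adjusted p = 7e-06; adjusted p = 0.817 with an estimated correlation), with 0 past over all genes and 8 adjusted over the list alone, SAMD9L (1.76 ± 0.38) and OAS2 (1.87 ± 0.42, its other probe set at 0.27) among them. Inflammatory genes had a median of 0.75 (18 measured, adjusted p = 0.0409; adjusted p = 0.817 with an estimated correlation), with 0 members past over all genes and 2 adjusted over the list alone, the neutrophil chemokine CXCL8 (2.12 ± 0.54) among them. CXCL9 differed by 2.56 ± 0.79, CXCL10 by 2.08 ± 0.66 and IFNG by 1.34 ± 0.71, and none passed. The macrophage and dendritic cell (median 0.20, adjusted p = 0.453) and mast cell lists (median -0.26, adjusted p = 0.453) did not pass against the pool. The immunoproteasome and antigen processing list did not pass (median 0.44, adjusted p = 0.453), and passed as higher after quantile normalization (list mean 0.39, adjusted p = 0.00174). The T cell (0.16, adjusted p = 0.443), interferon (0.14, adjusted p = 0.426) and inflammatory (0.59, adjusted p = 0.994) calls ended with the actin ratio as a covariate. After quantile normalization the T cell mean was 0.56 against 1.29. The inflammatory call also ended without affected replicate 1 (0.58, adjusted p = 0.0822), after quantile normalization (0.25, adjusted p = 0.272), without a filter (0.63, adjusted p = 0.304), with the mean of the probe sets (0.73, adjusted p = 0.0651) and in the probe sets with an above-median mean (0.63, adjusted p = 0.0799).

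Bulge and outer root sheath genes had a median log2 difference of -0.45 from the pool (23 measured, adjusted p = 0.0409) and cornified keratinocyte genes of -0.68 (30 measured, adjusted p = 0.00606), with 0 and 0 members past over all genes and 0 and 1 adjusted over the list alone. Both had adjusted p = 0.817 with an estimated correlation. KRT15 differed by -0.75 ± 0.59 and CYP1B1 by -0.42 ± 0.41, which turned to 0.092 after quantile normalization. Without affected replicate 2 they were -0.28 and -0.27. The bulge call ended without affected replicate 2 (list mean -0.18, adjusted p = 0.0982), after quantile normalization (-0.26, adjusted p = 0.253), with the stricter filter (-0.39, adjusted p = 0.101) and with the mean of the probe sets (-0.24, adjusted p = 0.162). The cornified mean was -0.26 without affected replicate 2, against -0.52, and still passed. Adjusting for the actin ratio turned the bulge mean to 0.69 without passing and the cornified mean to 1.27, past as higher. The fibrosis list did not pass (median -0.14, adjusted p = 0.183), and its mean turned from -0.17 to 0.044 after quantile normalization. Without a filter the list passed as lower (-0.17, adjusted p = 0.00374). COL1A1 differed by 1.38 ± 0.56, with its other probe sets between -0.52 and 0.87, and FN1 by -0.06 ± 0.39, which turned to 0.45 after quantile normalization, with its others between -0.01 and 1.26, and was -0.19 to 0.0056 without 1 array.

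Unaffected scalp was compared with the healthy pool, both occipital, which addresses what differs in FFA skin outside the lesion. Respiratory chain, mitochondrial ribosome, proteasome and sebaceous genes were lower in unaffected scalp as lists. 16 of 39 lists passed in limma camera, 4 higher and 12 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.772). Limma called 0 of 12339 genes (smallest adjusted p = 0.0744), with 932 at an unadjusted p under 0.05, 702 higher and 230 lower. The arrays did not overlap for 9538 genes, or 77.3%, where chance gives 66.7%. In the authors' deposited table, 209 genes were higher and 532 lower on both unaffected arrays (p under 0.001 or over 0.999). With only these groups in the fit limma called 20 genes, and without affected replicate 2 it called 5.

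The respiratory chain list had 61 of 67 measured members lower in unaffected scalp than in the pool (median log2 difference -0.37), the mitochondrial ribosome list 60 of 75 (median -0.39), the proteasome list 32 of 35 (median -0.51) and the sebaceous list 28 of 32 (median -0.62), each with adjusted p = 4.66e-06, and adjusted p = 0.772 with an estimated correlation. Beta-oxidation (18 of 18, median -0.52, adjusted p = 0.000178), antioxidant defence (30 of 36, median -0.39, adjusted p = 0.000399) and cholesterol synthesis genes (14 of 18, median -0.53, adjusted p = 0.00566) were lower as well, and also had adjusted p = 0.772 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 1 did, FADS2 in the sebaceous list (-2.92 ± 0.50). CYC1 differed by -1.57 ± 0.52, NDUFS3 by -0.83 ± 0.42, MRPL13 by -1.27 ± 0.44, PSMD3 by -1.44 ± 0.52, PSMC3 by -1.05 ± 0.42, HADHA by -0.93 ± 0.38, HMOX1 by -1.05 ± 0.41 and KRT79 by -1.55 ± 0.55. The 2 other Present probe sets of HADHA gave -0.76 and -0.22. The cholesterol gene SQLE differed by -0.99 ± 0.39, with its 2 other Present probe sets at 0.34 and 0.50. PPARG differed by -0.49 ± 0.55 (0.11 and -1.08 without unaffected replicates 1 and 2) and PPARGC1A by -0.43 ± 0.51.

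Single unaffected arrays carried much of these values. Without unaffected replicate 1 the list means were -0.23 for the respiratory chain (against -0.43), -0.23 for sebaceous genes (against -0.70) and -0.29 for beta-oxidation (against -0.55), all still past the threshold, and the cholesterol call ended (-0.19, adjusted p = 0.227). Without unaffected replicate 2 the sebaceous mean was -1.17 and the cholesterol mean -0.69, against -0.70 and -0.44. After quantile normalization the proteasome mean was -0.31, against -0.48. With the actin ratio as a covariate the means turned positive and passed as higher for the respiratory chain (2.07), proteasome (1.31), mitochondrial ribosome (1.18), sebaceous (1.29), beta-oxidation (1.05) and antioxidant lists (0.88), and turned positive without passing for cholesterol (1.05).

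Macrophage and dendritic cell (median log2 difference -0.41, adjusted p = 0.00679), mast cell (median -0.37, adjusted p = 0.00577), fibrosis (median -0.23, adjusted p = 0.00446) and cornified keratinocyte lists (median -0.26, adjusted p = 0.0227) were lower in unaffected scalp than in the pool, and keratin-associated proteins were higher (23 of 26, median 0.61, adjusted p = 0.0178). All had adjusted p = 0.772 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The complement gene C1QC differed by -1.52 ± 0.44, the mast cell proteases TPSAB1 and CTSG by -1.63 ± 0.47 and -1.15 ± 0.40, KRTAP4-7 by 1.02 ± 0.65, FN1 by -0.94 ± 0.41 (its others between -0.69 and 0.47) and CXCL9 by 0.61 ± 0.84 (1.26 and -0.038 without unaffected replicates 1 and 2). Without unaffected replicate 1 the macrophage (list mean -0.13, adjusted p = 0.37), cornified (-0.22, adjusted p = 0.0503) and keratin-associated protein calls (0.25, adjusted p = 0.599) ended. Without unaffected replicate 2 the macrophage mean was -0.63, against -0.38, and the keratin-associated protein mean 0.88, against 0.57. The latter was 0.28 after quantile normalization and 1.66 with the actin ratio as a covariate, and passed in both. With the actin ratio as a covariate the macrophage call ended (-0.07, adjusted p = 0.208), the mast cell (0.35) and fibrosis (0.17) means turned positive without passing, and the cornified mean turned to 1.04 and passed as higher.

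The genes of unaffected scalp with the largest moderated statistics against the pool did not pass. S100A7A differed by -3.96 ± 0.49, IGLC1 by -3.72 ± 0.48 (both adjusted p = 0.0744), the protease inhibitor SERPINB4 by -3.04 ± 0.63 and the pseudogene GUSBP11 by -1.86 ± 0.38. In the other direction MICAL3 differed by 2.83 ± 0.43, the cadherin CDH22 by 2.85 ± 0.48, CYP1A2 by 2.56 ± 0.43, SPEN by 2.26 ± 0.40 and the ribosomal protein gene RPL27A by 2.12 ± 0.37. MICAL3 was called Present on 1 unaffected array, and its other Present probe sets lay between -0.21 and 1.07. The other probe set of S100A7A gave -0.41, and those of SPEN gave 0.19 and 0.61.

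Differences from the pool correlated between affected and unaffected scalp across genes, which are not independent replicates. The log2 differences of the 12339 genes had a Pearson r of 0.85 and a Spearman rho of 0.813. Both comparisons share the pooled array, and 100 simulations of groups that do not differ gave a mean r of 0.707 (range 0.694 to 0.724) from the sharing alone. They drew the pool with the spread of the FFA groups. The observed covariance was 0.55, against 0.19 in the simulations, a difference of 0.36. The signs matched for 80.4% of genes, against 75.0% in the simulations. A pool that deviates by more than this spread would raise the simulated values. Part or all of the excess may come from the shared array itself, which cannot be split.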

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

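The filter on an above-median mean and the actin 3' to 5' ratio as a covariate were chosen after the data were seen, and every other alternative here was planned. The overlap of both comparisons with the pool had an r of 0.777 after quantile normalization, 0.810 without a filter, 0.825 to 0.848 without 1 affected array, and 0.773 and 0.817 without unaffected replicates 1 and 2. Simulated groups that do not differ gave a mean r of 0.707, 0.708, 0.664 to 0.667, 0.613 and 0.612 in these settings. These simulations also gave the pool the spread of the FFA groups. Of the single gene values under the alternatives, 1660 kept their direction and their side of the threshold, 101 no longer passed, 83 newly passed and 13 turned. Of the single list values, 846 kept both, 121 no longer passed, 5 newly passed and 35 turned. Dim signals limit what the arrays show, since the lowest signal called Present ranged from 24.7 to 71.3 between FFA arrays.

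The count of 186 genes in affected scalp against the pool was 84 after median centring, 100 with the stricter filter, 116 with the mean of the probe sets, 13 with pseudocount 64, 344 with pseudocount 1, 302 without the trend, 1089 over all probe sets one by one and 1 without a filter. It was 0 after quantile normalization and 0 with the actin covariate. In the deposited change p-values 652 genes changed on all 3 affected arrays and 741 on both unaffected arrays. Leaving out 1 array gave 0 to 825 genes for affected scalp against the pool, with 0 without affected replicate 1 and 825 without affected replicate 3, and 0 to 5 for unaffected scalp against the pool, with 5 without affected replicate 2. That comparison had 20 genes with only its groups in the fit and 2 with pseudocount 64, against 0. The estimated correlation, tested on 3 residual degrees of freedom, gave 0 lists in each comparison. Filters and the choice of probe set change how many genes are tested, and a left-out array, a block or a covariate changes the residual degrees of freedom. Beyond that the cause was not tested.

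With the replicate number as a block, affected against unaffected scalp gave 484 genes, and PPARGC1A turned to -0.26, as it did without affected replicate 3. The labels do not say that the numbers pair samples, and this fit has 1 residual degree of freedom.

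With the actin ratio as a covariate many list means turned. In affected against unaffected scalp they were 0.16 for antioxidant defence, 0.088 for beta-oxidation, 0.068 for heat shock, 0.017 for the inner root sheath, 0.25 for the mitochondrial ribosome, 0.23 for the proteasome and 0.39 for the respiratory chain. For affected scalp against the pool they were 1.04 for antioxidant defence, 0.99 for cholesterol synthesis, 1.27 for cornified keratinocytes, 1.14 for beta-oxidation, 0.41 for fibrosis, 0.69 for the bulge, 0.98 for heat shock, -1.10 for immediate early genes, 1.01 for mast cells, 1.43 for the mitochondrial ribosome, 0.66 for peroxisomes, 1.54 for the proteasome, 2.46 for the respiratory chain, 0.71 for sebaceous genes and 0.57 for ubiquitin conjugation. For unaffected scalp against the pool they were 0.88 for antioxidant defence, 1.05 for cholesterol synthesis, 1.04 for cornified keratinocytes, 1.05 for beta-oxidation, 0.17 for fibrosis, -0.88 for immediate early genes, 0.35 for mast cells, 1.18 for the mitochondrial ribosome, 1.31 for the proteasome, 2.07 for the respiratory chain and 1.29 for sebaceous genes. The pool's ratio lay outside the range of the FFA arrays, so its adjusted values are extrapolated.

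After quantile normalization the fibrosis mean of affected scalp against the pool turned to 0.044, the cytosolic ribosomal mean of unaffected scalp to -0.10, PPARGC1A in affected against unaffected scalp to -0.36, and CYP1B1 and FN1 in affected scalp against the pool to 0.092 and 0.45. FN1 was 0.34 with the mean of the probe sets, and MICAL3 in unaffected scalp was -0.21 with the stricter filter, which used another probe set. Leaving out 1 array gave -1.17 to 0.021 for PPARG and -0.26 to 0.24 for PPARGC1A in affected against unaffected scalp, -0.19 to 0.0056 for FN1 in affected scalp against the pool, and -1.08 to 0.11 for PPARG and -0.038 to 1.26 for CXCL9 in unaffected scalp against the pool. None of these genes passed the threshold. Of 130 named gene differences 23 moved by over 1.5 times or turned without 1 FFA array, 0 of them past the threshold with all arrays. List calls not described with their comparison also ended. In affected against unaffected scalp these were antioxidant defence with the mean of the probe sets (-0.15), heat shock with the stricter filter (-0.29) and the above-median filter (-0.24), and mast cells without a filter (0.35) and with the stricter filter (0.19). In unaffected scalp against the pool these were mast cells with the stricter filter (-0.46), cornified genes with only the groups compared (-0.28) and the above-median filter (-0.25), and keratin-associated proteins without a filter (0.46), with the mean of the probe sets (0.56) and with the above-median filter (0.46). The cause was not tested.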

Other observations

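The extra values given here for quantile normalization, beyond its calls, were chosen after it gave 0 calls, and the filter on an above-median mean and the actin covariate are alternatives added after the data were seen. Immediate early response genes, which are induced within minutes of a stimulus, were higher than in the pool in affected scalp (17 of 18 measured members, median log2 difference 1.20, limma camera, adjusted p = 0.00085; adjusted p = 0.817 with an estimated correlation) and in unaffected scalp (17 of 18, median 0.82, adjusted p = 0.000752; adjusted p = 0.772 with an estimated correlation). FOS rose over all genes in affected scalp (3.46 ± 0.57) and adjusted over the list alone in unaffected scalp (2.62 ± 0.60). In affected scalp 4 members passed adjusted over the list alone, CCN1 (2.65 ± 0.77) among them, and in unaffected scalp DUSP1 differed by 1.55 ± 0.59. The list mean was -1.01 on the pool and ranged from -0.52 to 0.42 on unaffected and from -0.49 to 1.20 on affected arrays. Without unaffected replicate 2 the call in unaffected scalp ended (0.49, adjusted p = 0.0939), and with the actin ratio as a covariate both means turned, to -1.10 and -0.88, and passed as lower. Smooth muscle and arrector pili genes were lower than in the pool in affected (12 of 13, median -0.89, adjusted p = 0.000395; adjusted p = 0.817 with an estimated correlation) and unaffected scalp (11 of 13, median -0.84, adjusted p = 1.89e-05; adjusted p = 0.772 with an estimated correlation), with PLN past over all genes in affected scalp. The contractile gene TAGLN differed by -1.43 ± 0.46 in affected and CNN1 by -1.46 ± 0.40 in unaffected scalp. With the actin covariate these calls ended (-0.31, adjusted p = 0.2, and -0.33, adjusted p = 0.133).

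Cytosolic ribosomal protein genes were higher in unaffected scalp than in the pool (39 of 42 measured members, median log2 difference 0.53, adjusted p = 0.00446; adjusted p = 0.772 with an estimated correlation), with RPLP2 at 1.24 ± 0.41. Their mean turned to -0.10 after quantile normalization, and the call ended without unaffected replicate 2 (0.44, adjusted p = 0.142) and without a filter (0.52, adjusted p = 0.201), while the mean was 2.27 with the actin covariate. Eccrine sweat gland genes were also higher there (11 of 15, median 0.83, adjusted p = 0.0497; adjusted p = 0.772 with an estimated correlation). This call ended without unaffected replicate 1 (0.57, adjusted p = 0.112), without affected replicate 1 (0.66, adjusted p = 0.0654), without a filter (0.44, adjusted p = 0.286), with pseudocount 1 (0.71, adjusted p = 0.0644), with the mean of the probe sets (0.68, adjusted p = 0.0894) and in the probe sets with an above-median mean (0.54, adjusted p = 0.101). With the actin ratio as a covariate the eccrine mean was 1.99, against 0.66 without it, and passed. No list other than those of this section and the ones described before passed in any comparison.

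The sebaceous and lipid synthesis list lay lower in affected than in unaffected scalp by 1.26 log2 units in the list mean (-1.26). RNA quality, read from the actin ratio (the GAPDH ratio did not part the FFA groups in the same way), remains open. With the log2 actin ratio as a covariate the difference was -0.58, nearer to 0 than the bound of -0.63 set before the test. The prediction for RNA quality as a cause was thus met. The 95% interval, -3.11 to 1.96 on 2 residual degrees of freedom, held 0 and the unadjusted difference, so the test does not decide. The interval without the covariate, -3.01 to 0.48, held 0 as well, while limma camera still called the list (adjusted p = 1.43e-07). Affected replicate 3 had a ratio of 7.67, close to the unaffected arrays, and a list mean of -0.29 against 0.05 and 0.98, a single array that decides nothing. Scalp region cannot be told apart from disease state, since 0 arrays held occipital affected or frontal unaffected scalp. Loss of sebaceous glands with the disease may account for the pattern and was not tested apart from these.

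Of the 186 genes called in affected scalp against the pool, 167 were higher. A filter that uses calls of the FFA arrays only remains open: with the above-median filter 90.9% of the 164 calls were higher (149), but 5 of the 6 arrays in that mean are FFA arrays, so it keeps the selection at issue and the bound set for it decides nothing, and without a filter limma called 1 gene, which was lower, with 3039 of 4179 genes higher at an unadjusted p under 0.05. Probe sets that do not follow their gene's transcript remain open: over the 52 of 167 higher genes with another Present probe set, the others had a median log2 difference of 1.13 against 2.52 for the chosen ones, between the bounds set for either reading. Array scaling that lifts dim probe sets on weak arrays remains open as well: after quantile normalization there were 0 calls, so the planned share could not be computed, and the higher genes' median was 1.88 (quartiles 1.58 and 2.41) against 2.69 before (2.33 and 3.15) at a median SE of 0.51 against 0.50, all 167 still above 0. Of these genes 166 kept an unadjusted p under 0.05. All genes at that level fell from 2701 (1725 higher) to 1317 (829 higher, or 62.9%), and the smallest adjusted p was 0.320. Why the calls ended was not tested, and disease cannot be told apart from scaling for the 167 higher genes.

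The respiratory chain and proteasome lists lay lower in both FFA groups than in the pool. Fold changes that fall with brightness remain open as a cause. In affected scalp 0% of 10000 random lists matched on brightness had a median as low as the respiratory chain's -0.86 (central 95% from -0.61 to -0.32). For the proteasome's -0.91 the share was also 0% (-0.67 to -0.23). The random lists had a median of -0.45 in both cases. In unaffected scalp the medians of -0.37 and -0.51 lay below the central 95% too (-0.21 to 0.03 and -0.27 to 0.05). Both lists thus lay below random lists of matched brightness. Random members were drawn independently, while members of these lists moved together (estimated correlations 0.88 and 0.70). The ranges are too narrow for such lists, so the test does not decide. For the respiratory chain list RNA quality cannot be told apart from disease, since 0 FFA arrays had an actin ratio at or under that of the pool, as for the GAPDH ratio, and with the ratio as a covariate the respiratory chain and proteasome means turned positive (2.46 and 1.54 in affected scalp). A disease effect, a difference in RNA quality and fold changes that fall with brightness may each contribute to the pattern.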
